A study of Mus musculus and Homo sapiens with 60 samples.

How the data were processed

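The data are RNA-seq libraries of 3 cell lines with normal or altered TRIM71 and ribosome profiling libraries of one of them. In all, 60 libraries were used, 52 of RNA and 8 of ribosome-protected fragments (RPF). Per the labels' protocols, the mouse embryonic stem cell (mESC) RNA libraries of batches 1 and 2 and of the experiment with 12 libraries were made with ScriptSeq kits, those of the LIF experiments, Ne4C and Huh-7 with a stranded TruSeq total RNA kit, and the RPF libraries with a TruSeq small RNA kit. RNA extraction differed between sets too, so levels are compared within an experiment.

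The deposited tables hold whole numbers with a different total in every column, read here as counts per gene with no normalization. That these are over exons for RNA and over coding sequence for RPF is taken from the table names; RNA tables whose names do not say so were read as exon counts too. STAR, without a version, and the builds mm10 and hg19 are named per the submitters' processing notes. The program that counted reads, the annotation version and the strand setting are not given in the sources used here. Reads of overlapping, antisense or near-identical genes may therefore be divided differently from their origin. The mouse RNA tables were joined on gene identifiers and gave 39017 genes, of which 37607 have a symbol and 31075 a chromosome in the RefSeq table of GRCm38, the same build as mm10. The RPF table has 23035 genes, 22205 with a symbol and 21169 with a chromosome. The Huh-7 table has 23358 genes named by symbol, and human coordinates were not used here. Coordinates are 1-based positions on GRCm38. The tables hold 84 more columns of sample values, which belong to none of the samples analysed here and were not used. No 2 of the count columns were identical.

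Groups were taken from the labels: 10 WT, 10 KO, 5 NHL and 5 RING mESC RNA libraries, 8 WT and 8 KO of Ne4C, 3 and 3 of Huh-7, and 4 and 4 of RPF. The labels number replicates within an experiment. Columns were matched by the names that the sample descriptions give. For the 12-library experiment these names occur in another table than the one named, and for the first LIF experiment the only WT and KO columns with LIF were taken. For the first WT and KO replicates of RPF batch 1 the descriptions give other names, and their columns were matched by batch, genotype and number.

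Total counts, in units of 1e+06, ran from 14.4 to 17.4 in batch 1, from 4.77 to 19 in batch 2, from 13 to 16.7 in the 12-library experiment, from 8.22 to 9.06 in the first LIF experiment and from 33.8 to 36.6 in the second. They ran from 8.01 to 9.07, from 35.4 to 39.8 and from 35.9 to 50.4 in the 3 Ne4C experiments, from 28 to 29.7 in Huh-7, from 2.46 to 8.9 in RPF batch 1 and from 1.14 to 2.48 in RPF batch 2. The deeper experiments have the smaller counting error, and the RPF libraries the largest.

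Each comparison was tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr, libraries scaled by TMM, dispersions estimated robustly, and the quasi-likelihood F test applied with Benjamini-Hochberg adjustment at 0.05. There were 13 comparisons. KO was compared with WT in mESCs over all 20 libraries with a term for the experiment, and in Ne4C likewise. The mESC mutants were compared with WT, KO and each other in 1 fit of the 20 libraries from the 2 experiments that hold all 4 genotypes, with a term for the experiment. Huh-7 had no covariate. RPF, and RNA of the same batches, had a term for the batch. Translational efficiency was the interaction of genotype and assay in 1 fit of the 8 RPF and 8 RNA libraries, with TMM within each assay and a batch term per assay. The difference of the KO effects of Ne4C and mESCs was an interaction in 1 fit of 36 libraries.

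Levels are CPM, counts per 1e+06 of the total after TMM scaling, which is not the total of counts itself. For Trim71, Mbnl1 and Ccr4 the scaling was over all libraries of the same line and assay, and for other genes over those of the comparison, so they compare levels within these sets. Log2 fold changes are edgeR's, which add a prior count to each value, and their SEs come from the same fit. A fold against a group with 0 counts is a bound against a floor of 3 counts over the group, and folds against 1 to 3 counts carry 95% Poisson counting intervals. Intervals and floors cover counting error only.

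Named genes follow a rule set before the data were examined. They are Trim71 and Mbnl1 in every comparison, and the 10 largest rises and 10 largest falls among genes that passed the test, had an average log2 CPM over 1 and had the same sign in every experiment. In the tests between mutants and KO, the interaction and translational efficiency the number was 5 each, and of the calls shared by Ne4C and mESCs 10 each, by the smaller of the 2 changes and at any level. Members of a fixed list come from the up to 4 with the smallest adjusted p. Predicted genes and pseudogenes were counted but not named, and some genes that the rule selects are not reported here. Genes outside this rule are those of the weighed patterns, Plppr4, and genes shown beside the value of another comparison; they were chosen after their values were seen. The tests, alternatives and gene lists were also fixed before the data were examined, apart from the additions named as such.

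The 25 gene lists covered earlier TRIM71 targets, splicing regulators, let-7 targets and LIN28, microRNA factors, naive pluripotency, primed epiblast, neural, glial, mesoderm, endoderm, 2-cell-like, germ cell, fibroblast, G1/S regulators, S phase and mitosis, p53 targets, stress response, immediate early and MAPK feedback, imprinted, Y-linked, cholesterol, hypoxia and glycolysis, hepatocyte, epithelial-mesenchymal and extracellular matrix genes. Each with at least 3 tested members was tested with camera, which compares it with all other genes, at a preset correlation of 0.01 and with an estimated one, adjusted over the lists of a comparison. The 2-cell-like list had 0 tested members in every comparison, so that state was not measured. Human genes were matched to lists and to mouse genes by symbol in capitals.

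Shared WT libraries raise the overlap of the mutant comparisons. It was set beside 10 simulations of unchanged groups, the overlap of independent lists, splits of the WT libraries, and KO calls from the 3 experiments without mutants. Overlaps between cell lines were tested with Fisher's exact test.

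Alternatives were DESeq2 1.42.0 with its size factors, upper-quartile scaling, no filter on low counts, a replicate block, glmTreat against 1.5-fold, each experiment alone or left out, each library left out, no experiment term and limma 3.58.1 voom with quality weights. For translational efficiency, TMM over all 16 libraries and a minimum of 50 RPF counts per genotype were added to these. The pipeline was tested on simulated counts with the means and library sizes of these samples, in which 200 genes were changed, 100 of them by each fold size. The edgeR test recovered 67% of 1.5-fold and 81% of 2-fold changes for KO in mESCs over 18420 genes, 69% and 93% in Ne4C over 17899, 73% and 89% in Huh-7 over 14664, 42% and 91% in RPF over 10283, and 10% and 57% for translational efficiency over 12851. For NHL, RING and KO against WT in the 2 shared experiments it recovered 55%, 67% and 52% of 1.5-fold changes and 79%, 84% and 82% of 2-fold changes over 16891 genes. It recovered 33% and 74% in RNA of the RPF batches and 56% and 66% for the difference between lines. In all 13 comparisons 0 changed genes were called in the wrong direction, and 2.3% to 11.4% of calls were false, the most for translational efficiency.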

Results

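RNA was sequenced from 3 cell lines with normal or altered TRIM71, an RNA-binding ubiquitin ligase with a RING domain at its N terminus and NHL repeats, which bind RNA, at its C terminus. Mouse embryonic stem cells (mESCs) of a 129xC57BL/6 background, grown on gelatin in serum with LIF, gave 10 wild-type (WT) and 10 Trim71 knockout (KO) libraries from 5 experiments. In 2 of these experiments there were also 5 libraries of a line homozygous for R738A, called NHL here, and 5 of a line homozygous for C12A and C15A, called RING here. The mouse neural progenitor line Ne4C gave 8 WT and 8 KO libraries from 3 experiments, and the human hepatoma line Huh-7 gave 3 and 3. Ribosome-protected fragments (RPF), which count ribosomes on each transcript, came from 4 WT and 4 KO mESC samples of 2 batches that also have RNA libraries. Total gene counts per library, in units of 1e+06, ranged from 4.77 to 36.6 in mESC RNA, from 8.01 to 50.4 in Ne4C, from 28 to 29.7 in Huh-7 and from 1.14 to 8.9 in RPF. The labels do not state that replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. They name no independent clones, so a difference between genotypes is one between the lines sampled.

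Trim71 RNA followed the genotype labels in the mouse lines. Trim71 (ENSMUSG00000079259, chromosome 9 of GRCm38, 114511268 to 114564369) was at 695 ± 127 CPM (counts per 1e+06 of the TMM-scaled library total; mean ± SD, n = 10) in WT mESCs and at 115 ± 39.1 CPM in KO mESCs (n = 10). Each KO library lay below each WT library. RPF libraries gave 99.3 ± 7.8 CPM in WT and 27.4 ± 3.69 CPM in KO (n = 4 each). NHL libraries had 529 ± 40.3 CPM and RING libraries 762 ± 105 CPM (n = 5 each, from 2 experiments). In these 2 experiments the WT means were 814 and 614 CPM. In Ne4C the level was 464 ± 124 CPM in WT and 54.9 ± 16.1 CPM in KO (n = 8 each). Human TRIM71 was at 102 ± 9.27 CPM in Huh-7 WT and 84 ± 3.78 CPM in Huh-7 KO (n = 3 each), a log2 fold change of -0.29 that passed the test (adjusted p = 0.00516, edgeR quasi-likelihood test) but not without WT replicate 3 (-0.22, adjusted p = 0.0515; 0.00233 to 1 over its alternatives, the highest against a 1.5-fold change). A knockout allele can keep its transcript, so this level does not check the Huh-7 labels.

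Mbnl1, a splicing regulator that the study links to TRIM71 (ENSMUSG00000027763, chromosome 3, 60472559 to 60629750), had more RNA in the KO lines and in NHL cells. Its log2 fold change was 0.98 ± 0.07 (SE) in KO mESCs (adjusted p = 5.33e-10, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment) and lay between 0.88 and 1.21 in each of the 5 experiments. It was 1.07 in NHL mESCs, 1.29 in KO Ne4C cells and 0.50 for MBNL1 in KO Huh-7 cells, and each passed the same test. In RING mESCs it was 0.02 and did not pass. The mean levels in mESCs were 21.5 ± 14.7 CPM in WT, 42.1 ± 27.2 in KO, 66.9 ± 15.5 in NHL and 32.8 ± 10.7 in RING. Levels differed between experiments, which used different library kits, and the experiment was a term of each fit.

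Ccr4, which encodes a chemokine receptor and ends 5792 bp before Trim71 (ENSMUSG00000047898, chromosome 9, 114490316 to 114505476), had the largest rise among the genes named in KO mESCs, NHL mESCs and KO Ne4C cells. Its level was 0.234 ± 0.178 CPM in WT mESCs and 66.1 ± 21.6 in KO (n = 10 each, 5 experiments). It was 38.3 ± 14.2 in NHL and 0.37 ± 0.243 in RING (n = 5 each, 2 of these experiments). In Ne4C it was 0.146 ± 0.107 CPM in WT and 44.5 ± 5.67 CPM in KO. All 23 KO and NHL mouse RNA libraries lay above all 23 WT and RING libraries.

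**Figure D1:**
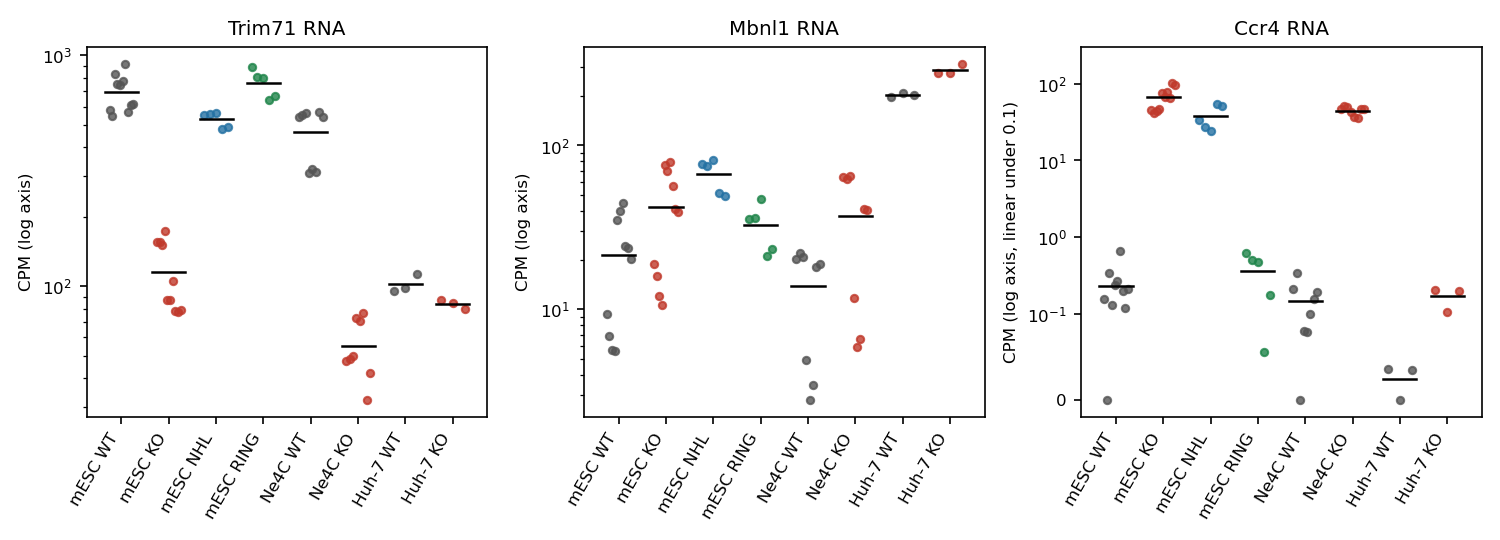
RNA of Trim71, Mbnl1 and Ccr4 in every RNA library, in CPM of the TMM-scaled library total on log axes (linear under 0.1 for Ccr4); each point is 1 library, black lines are group means, and Huh-7 points are the human genes. The 10 mESC KO libraries lie between 77.4 and 173 CPM of Trim71, below the 10 WT libraries, and Ccr4 is high in the KO and NHL libraries of the mouse lines.

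The first comparison asked what changes in mESCs without TRIM71. Genes of the primitive endoderm, an extraembryonic lineage, were lower in KO cells. The endoderm transcription factor Gata4 was at 14.3 ± 6.84 CPM in WT and 3.02 ± 2.75 CPM in KO (n = 10 each), a log2 fold change of -2.48 ± 0.43 (SE). Gata6 (-2.18), Sox17 (-2.32), the receptor Pdgfra (-2.15) and the endocytic receptors Cubn (-2.50) and Lrp2 (-2.47) fell too. Dnmt3a, a de novo DNA methyltransferase, went from 209 ± 73.3 to 80.8 ± 23.4 CPM and fell by 1.33 on the log2 scale. Among naive pluripotency factors Klf4 rose from 120 ± 44.3 to 198 ± 51.8 CPM (0.78 ± 0.09), Prdm14 by 0.67 and Nr5a2 by 0.64. In all, 2480 genes rose and 2649 fell of 18420 tested (edgeR quasi-likelihood test, adjusted p under 0.05). By more than 2-fold these were 352 and 332, and 3596 of the called genes had the same sign in all 5 experiments. Between pairs of experiments the log2 fold changes had r between 0.28 and 0.62 across genes, which are not independent replicates.

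After Ccr4 (8.38 ± 0.16), the largest rises with the same sign in all experiments were those of Usp26 (3.00), Rec114 (2.92), Pof1b (2.86), Itpr2 (2.82), Rgcc (2.76), Tex13b (2.70), Vax2 (2.57), Mageb4 (2.51) and Sohlh2 (2.36). Rec114 serves meiotic double-strand breaks and Sohlh2 is a germ cell transcription factor. Beside Trim71 (-2.65 ± 0.14) and the endoderm genes above, Foxq1 (-2.45), Nxf7 (-2.27) and Spink1 (-2.24) had the largest falls. Pof1b, Tex13b and Nxf7 lie on the distal X chromosome, a region that stood higher in RING cells and had a median log2 fold change of -0.03 in these KO cells.

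Among gene lists fixed before the data were examined, endoderm markers fell as a group: 10 of 14 measured members fell and 0 rose, or 11 and 0 adjusted over the list alone (camera adjusted p = 4.01e-06, or adjusted p = 0.264 with an estimated correlation). Of 12 markers of the formative or primed epiblast 7 fell and 0 rose in both counts, among them Zic2 (-1.68), Dnmt3b (-0.53) and Pou3f1 (-0.91; adjusted p = 2.32e-05, or adjusted p = 0.0542 with an estimated correlation). Of 22 naive pluripotency factors 12 rose and 3 fell, or 12 and 6 adjusted over the list alone, with Fbxo15 (-0.60) among the falls (adjusted p = 0.00389, or adjusted p = 0.189 with an estimated correlation). Of 16 cholesterol genes 12 rose and 0 fell, or 15 and 0 adjusted over the list alone, such as Insig1 (0.54), Msmo1 (0.47) and Cyp51 (0.46; adjusted p = 1.04e-05, or adjusted p = 0.264 with an estimated correlation). Of 21 let-7 microRNA targets and LIN28 genes 11 fell and 2 rose, or 11 and 3 adjusted over the list alone, with Mycn (-0.65), Hmga2 (-0.82) and Lin28a (-0.54; adjusted p = 0.00537, or adjusted p = 0.292 with an estimated correlation). Of 20 p53 targets 9 fell and 2 rose in both counts, including Sesn2 (-0.76) and Mdm2 (-0.45; adjusted p = 0.00491, or adjusted p = 0.546 with an estimated correlation). The p53 call was lost without the 12-library experiment that holds 4 genotypes (adjusted p = 0.194), and in the RNA of batches 1 and 2 alone 7 of the 20 rose and 2 fell (0.618).

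Of 8 transcripts named earlier as TRIM71 targets 3 rose and 1 fell, over all genes and adjusted over the list alone. Mbnl1, the cell-cycle repressor Rbl1 (0.78) and the EGR co-repressor Nab2 (0.53) rose, and the immediate early factor Egr1 fell by 1.96 on the log2 scale (adjusted p = 0.0169 for the list, or adjusted p = 0.334 with an estimated correlation). The study's authors chose part of this list, so it is not independent evidence. Of 20 imprinted genes 5 fell and 2 rose, or 6 and 2 adjusted over the list alone, with Nnat at -1.99 and Dlk1 at -1.67 (adjusted p = 0.0386, or adjusted p = 0.493 with an estimated correlation). Of 16 extracellular matrix genes 7 fell and 1 rose in both counts; 4 of the 16 were endoderm markers too (adjusted p = 0.0386, or adjusted p = 0.546 with an estimated correlation). Of 7 measured mesoderm markers 3 fell and 0 rose in both counts, Cdx2 (-2.49) and Wnt3 (-2.11) among them, which were at 0.476 ± 0.247 and 0.789 ± 0.458 CPM in WT (adjusted p = 0.0386, or adjusted p = 0.242 with an estimated correlation). These last 3 calls were lost without batch 1 and without either LIF experiment, with adjusted p between 0.0566 and 0.241.

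The other lists did not pass in KO mESCs. Their counts of rises and falls were the same adjusted over the list alone unless stated. Of 32 splicing regulators 3 rose and 4 fell (adjusted p = 0.981), and of 12 microRNA factors 2 and 2 (2 and 3 adjusted over the list alone; 0.536). Of 18 S phase and mitosis genes 2 rose and 1 fell (2 and 0; 0.589), and of 22 G1/S regulators 6 and 6 (7 and 6; 0.818). Hypoxia and glycolysis genes gave 5 rises and 0 falls among 16 (0.109), germ cell genes 4 and 1 among 13 (0.0999) and stress response genes 1 and 6 among 16 (3 and 7; 0.246). Immediate early and MAPK feedback genes gave 1 and 4 among 17 (0.53), neural markers 3 and 3 among 15 (0.818) and glial markers 0 and 3 among 7 (0.351). Epithelial-mesenchymal markers gave 2 and 6 among 16 (0.403) and hepatocyte genes 1 and 1 among 10 (0.809). Fibroblast markers, which would show feeder or stromal cells, gave 0 and 3 among 12 (0.403). Without the 12-library experiment germ cell genes (0.0216) and hypoxia genes (0.000162) passed as higher and fibroblast markers (0.00788) as lower. In the germ cell, MAPK, G1/S, splicing and hepatocyte lists the median, mean and test differed in sign. Of 4 Y-linked genes 2 were measured, too few for a list test, and 1 fell. Of 10 markers of the 2-cell-like state 0 had enough counts, here and in the other comparisons.

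The second comparison asked whether a change in the NHL repeats or in the RING domain acts like the loss of TRIM71, in the 2 experiments with 5 libraries per genotype. Endoderm genes were lower in all 3 altered lines. Gata6 was at 7.89 ± 5.33 CPM in WT, 0.747 ± 0.18 in KO, 0.746 ± 0.585 in NHL and 0.391 ± 0.259 in RING, with log2 fold changes of -3.39 ± 0.24, -3.33 ± 0.23 and -4.25 ± 0.26 (SE). Nanog, a core factor of naive pluripotency, was at 219 ± 8.96 CPM in WT and rose to 486 ± 11.2 in KO, 469 ± 19.2 in NHL and 383 ± 30.5 in RING. Dnmt3a had log2 fold changes of -1.68, -1.63 and -1.5. Mbnl1 and Ccr4 rose in KO (0.92 and 8.48) and in NHL (1.07 and 7.31). Mbnl1 was lower in RING than in KO by a log2 fold change of -0.90, and Ccr4 by -8.33, and both differences passed the test.

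Of 16891 genes tested, 1965 rose and 1768 fell in KO, 2178 and 2232 in NHL, and 1949 and 1810 in RING (edgeR quasi-likelihood test, adjusted p under 0.05). KO and NHL shared 1491 rises and 1351 falls, where independent lists would share 253 and 234. KO and RING shared 956 and 895, against 227 and 189, and NHL and RING 972 and 980, against 251 and 239. Across genes the log2 fold changes had r = 0.81 between KO and NHL, 0.52 between KO and RING and 0.64 between NHL and RING. All 3 share their WT libraries, and in 10 simulations of unchanged groups against those libraries r averaged 0.5. The r of 0.52 between KO and RING is therefore by itself no sign of shared effects. Without a shared library, r between KO and RING was 0.5 in both splits of the WT libraries given below. It was 0.41 with KO from the other 3 experiments, so shared libraries are not the only source of this correlation. Simulated calls averaged 0.2 and shared calls 0. With so few calls, the simulations cannot show how far shared libraries raise the overlap of called genes. The covariance, to which shared controls add the same amount with or without real effects, was 0.119, 0.0794 and 0.107 for the 3 pairs against 0.0108 simulated. With the WT libraries split so that no library served both sides, KO and NHL shared 624 or 770 rises and 519 or 692 falls, and KO and RING 288 or 290 rises and 313 or 305 falls. With KO calls from the other 3 experiments, which share no library with the mutants, NHL shared 854 rises and 642 falls (226 and 171 for independent lists) and RING 670 and 446 (203 and 137).

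Over the 1742 genes that rose in those other experiments, the median log2 fold change was 0.33 in KO, 0.30 in NHL and 0.22 in RING. Over the 1267 that fell it was -0.28, -0.33 and -0.20. Tested directly, 38 genes were higher and 28 lower in NHL than in KO, 1108 higher and 1209 lower in RING than in KO, and 1492 higher and 1537 lower in NHL than in RING. Which direction had more genes depended on scaling or tool: RING had 1270 higher and 1081 lower than KO with upper-quartile scaling, and NHL 2086 and 1579 than RING by DESeq2. Of the 1965 genes that rose in KO, 616 differed from KO toward WT in RING and 7 in NHL. Of the 1768 that fell, 368 and 32 did.

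Endoderm markers were lower as a group in each line, and their calls held with an estimated correlation. Of 14 members 10 fell and 0 rose in KO (adjusted p = 1.63e-20, or adjusted p = 0.0292 with an estimated correlation), 12 and 0 in NHL (3.9e-20, or adjusted p = 0.0158 with an estimated correlation) and 13 and 1 in RING (5.57e-27, or adjusted p = 0.0073 with an estimated correlation). Each count was the same adjusted over the list alone. The 1 that rose was the chemokine receptor gene Cxcr4 (0.80). Of 11 primed epiblast markers 6 fell in KO, 6 in NHL and 5 in RING, with 1, 0 and 0 rises (adjusted p = 0.00122, 0.000109 and 0.00136, or adjusted p = 0.297, 0.181 and 0.247 with an estimated correlation). Of 22 naive factors 10, 10 and 12 rose and 3, 4 and 3 fell (adjusted p = 0.000391, 0.00606 and 0.00205, or adjusted p = 0.244, 0.394 and 0.247 with an estimated correlation). Of 19 p53 targets 12, 12 and 8 fell and 1 rose in each line, Trp53inp1 at -0.96, -1 and -0.75 (adjusted p = 2.89e-08, 7.72e-07 and 0.00978, or adjusted p = 0.0584, 0.101 and 0.375 with an estimated correlation). Adjusted over the list alone, primed markers gave 6, 6 and 5 falls with 1, 1 and 0 rises, naive factors 10, 12 and 13 rises with 3, 4 and 3 falls, and p53 targets 14, 13 and 8 falls with 1, 2 and 1 rises.

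**Figure D2:**
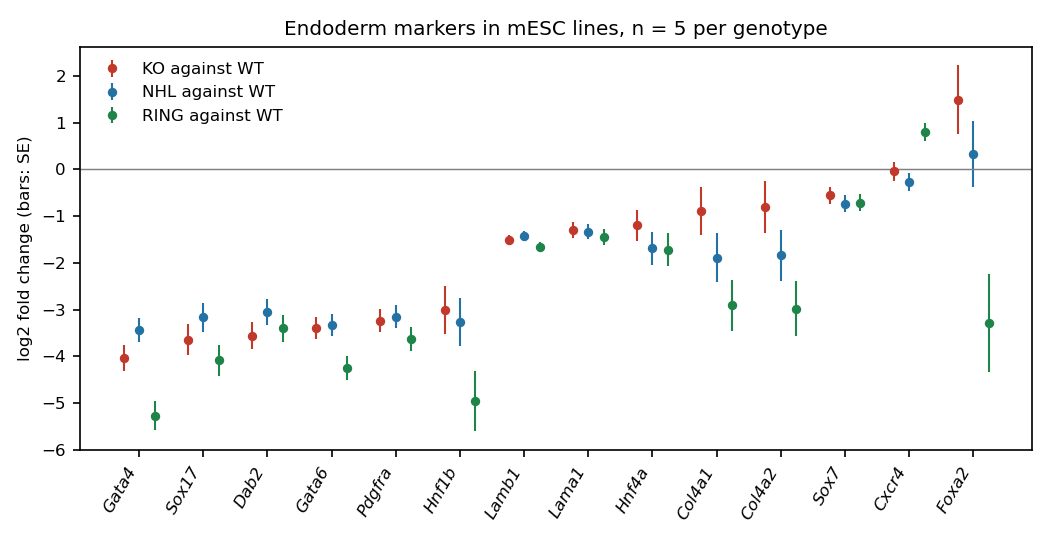
Log2 fold changes of the 14 measured endoderm markers in KO, NHL and RING mESCs against WT; points are fitted values, bars are standard errors, and each genotype has 5 libraries. Gata4 lies at -4.03 in KO, -3.44 in NHL and -5.27 in RING.

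Of 16 matrix genes 5 fell in KO, 6 in NHL and 8 in RING, with 0, 2 and 0 rises, Lamb1 and Lama1 of the endoderm list among the falls (adjusted p = 0.00249, 0.00606 and 1.52e-07, or adjusted p = 0.69, 0.688 and 0.247 with an estimated correlation). Adjusted over the list alone there were 6, 6 and 10 falls and again 0, 2 and 0 rises. The let-7 list passed in NHL, with 9 falls and 2 rises among 21 (10 and 2 adjusted over the list alone; adjusted p = 0.0244, or adjusted p = 0.688 with an estimated correlation), and in RING, with 5 and 1 (9 and 2; adjusted p = 0.0143, or adjusted p = 0.514 with an estimated correlation). In RING 4 lists passed that did not pass in KO or NHL of these experiments, which is no test of a difference; tested against KO, 3 of them differed, as given below, and cholesterol genes did not (0 of 16 called, median 0.06, adjusted p = 0.694; KO against WT: median 0.21, adjusted p = 0.07). Of 15 hypoxia and glycolysis genes 5 rose and 0 fell, or 8 and 0 adjusted over the list alone (adjusted p = 0.00553, or adjusted p = 0.514 with an estimated correlation). Among them the glycolytic enzyme gene Pgk1, which lies in the distal X region described below, went from 175 ± 21.1 to 414 ± 28.1 CPM. Of 16 cholesterol genes 7 rose and 0 fell, or 8 and 0 adjusted over the list alone (adjusted p = 0.0088, or adjusted p = 0.514 with an estimated correlation), and of 12 germ cell genes 3 rose and 0 fell in both counts, Tex19.1 (1.22) among them (adjusted p = 0.0342, or adjusted p = 0.347 with an estimated correlation). Of 15 epithelial-mesenchymal markers 6 fell and 0 rose, or 8 and 0 adjusted over the list alone; Krt8 (-0.90) and Epcam (-0.35) are epithelial and Zeb2 (-1.52) is mesenchymal (adjusted p = 0.00313, or adjusted p = 0.247 with an estimated correlation).

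Of 20 imprinted genes 9 fell and 0 rose in NHL (adjusted p = 7.72e-07, or adjusted p = 0.194 with an estimated correlation) and 10 and 0 in RING (adjusted p = 8.62e-10, or adjusted p = 0.196 with an estimated correlation), with the same counts adjusted over the list alone. Leading them were 3 noncoding RNAs expressed from the maternal allele of chromosome 12 (GRCm38, 109540996 to 109749458). Meg3 went from 55.9 ± 16.5 CPM in WT to 0.596 ± 0.459 in NHL and 0.202 ± 0.129 in RING, Rian from 263 ± 81.1 to 2.17 ± 2.02 and 1.06 ± 0.343, and Mirg from 32.3 ± 8.23 to 0.213 ± 0.163 and 0.11 ± 0.12 (n = 5 each). In KO their log2 fold changes were -0.21, -0.09 and 0.07 and did not pass. The paternally expressed neighbour Dlk1 fell in all 3 lines (-1.56, -2.03 and -1.97). Over the other 17 imprinted genes the median was -0.05 in KO, -0.18 in NHL and -0.29 in RING.

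RING mESCs also differed along the X chromosome. Of 277 genes at or beyond 95 Mb, 152 rose and 15 fell, with a median of 0.65 and quartiles of -0.09 and 1.01. The median was 0.65 and 0.63 in the 2 experiments. Over the 300 genes nearer the start it was -0.06, and over the distal genes it was -0.03 in KO and 0 in NHL. Tex13b (3.58), the meiotic gene Tex11 (2.85) and Cnksr2 (2.13), all distal, were among the 10 largest rises in RING, while Mid1, near the end of X (169685199 to 169990798), fell by 4.14 on the log2 scale. The boundary was chosen after the data were seen. Without X-linked genes 3426 genes were called in RING against WT and 2033 against KO.

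Vax2, an eye homeobox gene, rose by 4.00 in KO and in NHL, and its antisense neighbour Vax2os by 3.01 and 3.07; the strand setting of the counting is not given, so their reads cannot be told apart. Itpr2, a calcium channel of the endoplasmic reticulum, rose by 4.12 and 3.10, Platr15 by 3.27 and 3.28 and the bicarbonate transporter gene Slc4a5 by 2.82 and 2.99. Pof1b (3.13, distal X), Adgrg6 (2.93) and Tmem108 (2.80) completed the largest rises in KO, and Rec114 (2.98), Hoxa10 (2.72), Olfml3 (2.69) and Sohlh2 (2.54) those in NHL. In RING they were St8sia6 (2.40), Sohlh2 (2.22), B3gnt3 (2.19), Tmem108 (2.11), Gpa33 (2.09), Rec114 (2.04) and A2m (2.03) beside the X-linked genes above. H19, an imprinted noncoding RNA, rose in KO (3.12) and fell in RING (-4.54). The proteoglycan gene Srgn had log2 fold changes of -4.11, -4.16 and -5.55 in KO, NHL and RING, Cubn of -4.31, -4.44 and -5.38 and Pdgfra of -3.24, -3.15 and -3.63. The endocytic adaptor Dab2 (-3.56 and -3.05) and Lrp2 (-3.48 and -3.43) were among the largest falls in KO and NHL, and Spink1 (-2.53) and Plac8 (-2.41) in KO.

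Tested against each other, NHL had more Hoxa10 (3.62), Nnat (2.60), Trim71 (2.59), S100a4 (2.49) and Fam198b (1.70) than KO and less Mirg (-7.25), Rian (-6.41), Meg3 (-5.85), Rhox5 (-1.63) and Repin1 (-1.21). RING had more Trim71 (3.13), Tex11 (2.21), Nnat (1.87), Pdzd11 (1.82) and Tsc22d3 (1.75) than KO and less Ccr4, Mirg (-8.20), Rian (-7.67), H19 (-7.66) and Meg3 (-7.55). NHL exceeded RING in Ccr4 (7.16), H19 (6.14), Mid1 (3.80), Foxa2 (3.61) and Hoxa10 (3.61) and lay below it in Bnip3 (-2.14), Tex11 (-2.09), Egln3 (-1.83), Tsc22d3 (-1.77) and Pdzd11 (-1.74). Tex11, Tsc22d3, Pdzd11 and Mid1 lie in distal X.

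Single libraries decided some of these calls. In NHL, Itpr2 did not pass without WT replicate 2 (3.14, edgeR adjusted p = 0.0539) or NHL replicate 2 (2.70, 0.054) of the second LIF experiment. Between NHL and KO, S100a4 did not pass without KO replicate 1 (2.25, 0.063) or 2 (2.35, 0.0573) of it, and Fam198b did not pass without either KO library (0.151 and 0.139) or either NHL library (0.105 and 0.127) of it. Between NHL and RING, Foxa2 did not pass without NHL replicate 1 (3.20, 0.0508) or RING replicate 1 (3.34, 0.0665) or 2 (3.66, 0.0549) of it. Egln3 did not pass without any of 8 of the 10 libraries (0.053 to 0.104), all but NHL replicate 1 and RING replicate 3 of the 12-library experiment. Over all alternatives the adjusted p ranged from 4.27e-14 to 0.192 for Itpr2, 8.96e-14 to 0.478 for S100a4, 1.62e-11 to 0.679 for Fam198b, 1.09e-10 to 0.154 for Foxa2 and 1.46e-15 to 0.437 for Egln3. Alone, the 12-library experiment gave 191 genes between NHL and KO, 58 higher and 133 lower in NHL, and the second LIF experiment 2584, 1372 and 1212. Without KO replicate 1 or 2 of the latter 41 or 43 genes differed, 16 higher and 25 lower or 17 and 26 instead of 38 and 28, so the balance of the 2 directions rests on single libraries.

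By list, NHL and KO differed in imprinted genes (3 lower and 1 higher of 20; 7 and 1 adjusted over the list alone; adjusted p = 1.52e-15, or adjusted p = 0.0528 with an estimated correlation). They differed in MAPK feedback genes as a group, with 0 of 15 called over all genes and 3 lower adjusted over the list alone (adjusted p = 0.0117, or adjusted p = 0.818 with an estimated correlation). RING differed from KO in 8 lists. Imprinted genes had 8 lower and 1 higher of 20 (9 and 1 adjusted over the list alone; adjusted p = 2.88e-07, or adjusted p = 0.379 with an estimated correlation), endoderm markers 4 and 1 of 14 (5 and 1; 0.0369), matrix genes 7 and 0 of 16 (7 and 0; 0.036) and epithelial-mesenchymal markers 3 and 0 of 15 (3 and 0; 0.036). Hypoxia genes had 2 higher and 0 lower of 15 (2 and 0; 0.00281), p53 targets 5 and 0 of 19 (5 and 0; 0.00993), with Pmaip1 at 1.05, glial markers 2 and 0 of 6 (2 and 0; 0.013) and germ cell genes 5 and 1 of 12 (7 and 1; 0.036). Their adjusted p = 0.625, 0.625, 0.625, 0.625, 0.524, 0.158 and 0.524 with an estimated correlation, in the same order. NHL was below RING in hypoxia genes, 6 of 15 with 0 higher (13 and 0 adjusted over the list alone; adjusted p = 7.44e-05), germ cell genes, 7 of 12 with 0 higher (7 and 1; 0.0249) and p53 targets, 5 of 19 with 0 higher (5 and 0; 0.0249), and above it in matrix genes, 4 of 16 with 0 lower (5 and 0; 0.0422). These had adjusted p = 0.738, 0.559, 0.738 and 0.767 with an estimated correlation.

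The third comparison took the knockout to neural progenitor cells. In Ne4C several genes went from clear expression to few or no counts. Rpp25, which encodes a subunit of ribonucleases P and MRP, had 1635 counts over the 8 WT libraries and 0 over the 8 KO libraries, at least 560-fold lower with a floor of 3 counts over the group. Snx19, a sorting nexin, was 792-fold lower (95% counting interval 271 to 3840) and Fam83g 438-fold lower (150 to 2120); intervals and floors cover counting error only. Hexa, a lysosomal hexosaminidase subunit, went from 18.7 ± 21.9 to 0.0496 ± 0.0406 CPM, Fgf4 from 10.7 ± 4.92 to 0.0438 ± 0.0844, the telomerase gene Tert from 5.88 ± 1.22 to 0.0116 ± 0.0166 and Gas6 from 8.4 ± 2.84 to 0.0452 ± 0.051. The epithelial genes Rab25 and Prss8 rose from 0.262 ± 0.107 to 9.1 ± 4.33 CPM and from 1.07 ± 0.617 to 6.53 ± 4.01 CPM.

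Of 17899 genes tested in Ne4C, 3936 rose and 3873 fell (edgeR quasi-likelihood test, adjusted p under 0.05), 534 and 813 by more than 2-fold. With upper-quartile scaling the split was 3201 and 4766, 40.2% rises instead of 50.4%. After Ccr4 (8.29) and Rab25 (5.33), the largest rises were those of the ascorbate transporter Slc23a1 (4.01), Bnipl (3.63), Lnx1 (3.28), Tmem184a (2.95), caveolin gene Cav1 (2.89), Lypd6b (2.72) and Tmem176b (2.67). She (-8.15) and Cyba (-7.67) completed the largest falls. Trim71 fell by 3.08 on the log2 scale. Between pairs of experiments r lay between 0.66 and 0.71 across genes.

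All 4 Y-linked genes rose in KO Ne4C cells, Ddx3y by 1.87, Eif2s3y by 1.34, Uty by 0.88 and Kdm5d by 0.82, in both counts (adjusted p = 2.45e-07, or adjusted p = 0.168 with an estimated correlation). Of 17 immediate early and MAPK feedback genes 10 rose and 1 fell, with the same counts adjusted over the list alone, among them the AP-1 factor Junb (1.38) and the feedback inhibitor Spry2 (0.76; adjusted p = 0.00676, or adjusted p = 0.349 with an estimated correlation). Of 21 G1/S regulators 13 rose and 3 fell in both counts: the inhibitors Cdkn2b (1.79) and Cdkn2a (1.10) and Rbl1 (0.51) rose and the cyclin gene Ccne1 fell by 0.46 (adjusted p = 0.0212, or adjusted p = 0.349 with an estimated correlation). The MAPK call was lost without the second experiment (adjusted p = 0.107) and the G1/S call without the first (0.0568). Neural markers did not pass, with 3 rises and 4 falls among 20 in both counts (adjusted p = 0.77), nor did glial markers, with 0 and 1 among 6 (0.112), or S phase and mitosis genes, with 0 and 8 among 18 (0.123). The earlier targets gave 5 rises and 0 falls among 8, or 6 and 0 adjusted over the list alone, which is not independent evidence (0.0607). Other calls were gained when 1 experiment was left out: lower fibroblast markers (0.0139) and higher stress response (0.000303) and cholesterol genes (0.000134) without the first, higher earlier targets and lower naive factors and S phase and mitosis genes without the second (0.0238 each), and higher earlier targets (0.0166) and p53 targets (0.00217) and lower hypoxia genes (0.00161) without the third.

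The knockout changed partly the same genes in Ne4C and mESCs. Of 16488 genes tested in both, 799 rose and 711 fell in both lines, where independent lists would share 477 and 536 (Fisher's exact test, two-sided, p = 6.86e-65 and 2.03e-19 across genes). The log2 fold changes had r = 0.11. The largest shared rises, in mESCs and Ne4C, were those of Ccr4 (8.38 and 8.29), the flippase gene Atp8b1 (2.58 and 3.47), Gpld1 (1.93 and 2.27), Lmcd1 (1.80 and 1.83), the adrenergic receptor gene Adrb1 (1.75 and 1.76), Vax2 (2.57 and 1.66), Serpinb1a (1.58 and 2.50), H19 (1.62 and 1.53), Tcim (1.29 and 1.47) and the ciliogenesis factor Foxj1 (1.29 and 1.29). Beside Trim71, the largest shared falls were those of the retinoid receptor Rxrg (-1.99 and -2.43), Tfap2e (-1.91 and -4.65), the DNA methylation cofactor Dnmt3l (-1.90 and -3.04), Plac8 (-1.75 and -3.25), En1 (-2.30 and -1.64), the piRNA factor Tdrd12 (-1.53 and -4.59), Amn (-1.47 and -4.25), Zic2 (-1.68 and -1.37) and the collagen cross-linking enzyme Lox (-1.37 and -5.54).

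Some of these calls rested on 1 experiment or on the tool. In mESCs, Gpld1 did not pass without batch 1 (2.09, edgeR adjusted p = 0.0915) or the 12-library experiment (0.45, 0.492), H19 without batch 2 (1.75, 0.0647), and Lox (-0.14, 0.866) and Tcim (1.38, 0.0584) without the second LIF experiment. In Ne4C, Serpinb1a did not pass without the second experiment (1.95, 0.0683) or Tcim without the first (1.05, 0.065), and by other tools H19 did not pass (DESeq2: 0.60, 0.393; limma-voom: 1.09, 0.126), nor did Vax2 by limma-voom (0.79 instead of 1.66, 0.213; 3.86e-05 to 0.213 over its alternatives). In mESCs Gpld1 did not pass by DESeq2 (1.47, 0.0958) or Lox by limma-voom (-1.54, 0.172). Over all alternatives the adjusted p ranged up to 0.492 for Gpld1, 0.305 and 0.447 for H19 in the 2 lines, 0.866 for Lox, 0.307 and 0.0767 for Tcim and 0.0683 for Serpinb1a; the lowest values were 6.32e-12, 4.52e-103, 0.000281, 2.09e-08, 2.77e-06, 0.00027 and 1.89e-07.

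The effect of the knockout differed between the lines for 5881 of 19517 genes, 2872 higher and 3009 lower in Ne4C (interaction term, edgeR quasi-likelihood test). For Mbnl1 and Trim71 the differences of 0.30 and -0.43 did not pass, but did without the second Ne4C experiment (0.40, adjusted p = 0.00975, and -1.03, adjusted p = 0.000501; 0.00975 to 1 and 4.71e-05 to 1 over all alternatives). Trim71 passed with no filter on low counts too (-0.45, adjusted p = 4.71e-05). Of the 5400 called genes tested in each line alone, 942 were called in both with opposite sign, 497 of them rising in Ne4C. Dnmt3a (1.46) and Egr1 (3.11) had more positive effects in Ne4C. Srgn (4.68), Rab25 (4.61), Cav1 (4.29), Zfpm2 (4.20) and Insm1 (3.90) led that direction, and Rpp25 (-10.31), She (-9.39), Kdf1 (-9.35), Snx19 (-9.34) and Hexa (-8.76) the other. Srgn did not pass without the second (4.69, adjusted p = 0.121) or the third Ne4C experiment (4.55, 0.0756; 1.79e-27 to 0.121 over all alternatives). Of 22 naive factors 6 were lower and 3 higher in Ne4C, or 7 and 4 adjusted over the list alone (adjusted p = 0.00096, or adjusted p = 0.0251 with an estimated correlation). Endoderm markers had 9 higher and 3 lower of 14 in both counts (adjusted p = 0.00939, or adjusted p = 0.496 with an estimated correlation), primed epiblast markers 6 and 0 of 12 in both (0.00165, or adjusted p = 0.0928 with an estimated correlation) and p53 targets 11 and 1 of 20 in both (0.000554, or adjusted p = 0.365 with an estimated correlation). MAPK feedback genes had 8 and 1 of 17 (10 and 1 adjusted over the list alone; 0.00103, or adjusted p = 0.203 with an estimated correlation), Y-linked genes 3 and 0 of 4 (4 and 0; 0.0434, or adjusted p = 0.496 with an estimated correlation) and hypoxia genes 0 and 8 of 16 (0 and 10; 0.00306, or adjusted p = 0.496 with an estimated correlation).

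The fourth comparison was the knockout in Huh-7 cells. Hepatocyte genes were higher and fibroblast markers lower in KO cells, while collagen genes changed in both directions. Albumin (ALB) went from 4410 ± 195 to 13400 ± 636 CPM (n = 3 each), a log2 fold change of 1.60 ± 0.07 (SE), TM4SF4 from 14.4 ± 1.22 to 138 ± 6.12 CPM and APOA2 from 932 ± 21.7 to 2200 ± 208 CPM. The fibrillar collagen gene COL1A2 went from 169 ± 3.14 to 20.6 ± 2.82 CPM and COL1A1 fell by 3.08 on the log2 scale. Of 14664 genes tested 3570 rose and 3354 fell, 810 and 589 by more than 2-fold (edgeR quasi-likelihood test, adjusted p under 0.05). The largest rises were those of the keratin KRT17 (7.08), COL16A1 (6.85), the alcohol dehydrogenase ADH1C (6.32), S100A14 (6.26), B3GNT3 (5.81), SFRP4 (5.78), ATOH8 (5.32), NUPR1 (5.28), FGL1 (5.06) and PRODH2 (4.92). DYNLT3, a dynein light chain, had 353 counts over the WT libraries and 0 over the KO libraries, at least 119-fold lower with a floor of 3 counts over the group. The Wnt inhibitor SFRP1 was 469-fold lower (84.2 to 18500), and ANK1 (-6.32), SLC7A8 (-5.53), HDGFL3 (-5.40), COL11A1 (-4.23), COLEC12 (-4.14), COL2A1 (-3.87) and ACTN3 (-3.81) followed.

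Of 23 hepatocyte genes 17 rose and 1 fell, or 18 and 1 adjusted over the list alone (adjusted p = 4.94e-09, or adjusted p = 0.32 with an estimated correlation). Of 8 fibroblast markers 5 fell and 0 rose in both counts (adjusted p = 4.94e-09, or adjusted p = 0.0679 with an estimated correlation). Of 15 cholesterol genes 12 fell and 0 rose in both counts, among them IDI1 (-0.97; adjusted p = 0.000386, or adjusted p = 0.32 with an estimated correlation). Of 18 S phase and mitosis genes 13 fell and 1 rose, or 14 and 1 adjusted over the list alone, with CDC20 at -0.75 and CCNB1 at -0.69 (adjusted p = 0.00114, or adjusted p = 0.32 with an estimated correlation). Of 15 epithelial-mesenchymal markers 5 rose and 4 fell, or 7 and 5 adjusted over the list alone; the integrin ITGA5 (1.66), the epithelial cadherin CDH1 (1.42) and EPCAM (0.96) rose (adjusted p = 0.0197, or adjusted p = 0.372 with an estimated correlation). Of 19 let-7 targets 9 fell and 4 rose, or 10 and 4 adjusted over the list alone, with MYCN at -1.58 (adjusted p = 0.042, or adjusted p = 0.32 with an estimated correlation). The earlier targets gave 4 rises and 1 fall among 8 in both counts (adjusted p = 0.0804).

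Of 10837 genes matched by symbol and tested in Huh-7 and mESCs, 528 rose and 515 fell in both (410 and 436 for independent lists; Fisher's exact test, two-sided, p = 1.22e-12 and 2.5e-06), with r = 0.06 across genes. All 3 lines shared 234 rises and 164 falls of 10391 genes, against 95.3 and 97.9 for independent lists. Ranked by the smallest of the 3 changes, a choice made after the values were seen, Plppr4 (1.08 in mESCs, 1.99 in Ne4C and 1.47 in Huh-7) led the rises and Plac8 (-1.75, -3.25 and -2.93) the falls. In mESCs Plppr4 did not pass by DESeq2 (adjusted p = 0.103; 0.014 to 0.662 over its alternatives).

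The fifth comparison set ribosome occupancy beside RNA in the same 2 batches of mESCs. RPF of the transglutaminase gene Tgm2 went from 69.1 ± 13.8 to 566 ± 56.1 CPM (n = 4 each), a log2 fold change of 3.06 ± 0.10 (SE) beside 2.77 ± 0.11 in RNA. Egr1 fell in both (-2.27 in RPF and -2.06 in RNA), as did Zic2 (-3.55 and -2.38). Mbnl1 RPF went from 1.81 ± 0.368 to 8.34 ± 1.77 CPM, a log2 fold change of 2.16 ± 0.32, from 32 counts over WT and 84 over KO. Ccr4 had 1 RPF count in WT and 195 in KO, a 333-fold ratio (95% counting interval 59.7 to 13100), and Usp26 was 39.3-fold higher (10.9 to 324). In RPF 1055 genes rose and 948 fell of 10283 tested, and in RNA of the same batches 1901 and 1416 of 16315 (edgeR quasi-likelihood test, adjusted p under 0.05). They shared 798 rises and 497 falls of 10260 genes (158 and 90.1 for independent lists), with r = 0.81 across genes. Without WT replicate 1 or 2 of batch 2 the RNA count was 2018 or 2133, and without WT replicate 1 of batch 1 it was 2064, instead of 3317.

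Rec114 (3.03 in RPF, 3.04 in RNA), Tex13b (2.97, 3.10), Rgcc (2.85, 3.05), Hal (2.70, 2.41) and Itpr2 (2.61, 2.34) were among the largest rises in both, with Alox12b (2.65) and Sohlh2 (2.31) in RPF and Dnajb13 (2.44), Cntnap2 (2.36) and Myl3 (2.36) in RNA. Crmp1 (-2.28, -2.11), Tagln (-2.37, -1.92) and Trim71 (-1.85, -2.07) were among the largest falls in both, with Vgf (-2.10), Glipr2, Ets1 (-1.91), Gap43 (-1.84) and Krt18 (-1.82) in RPF and Pax6 (-3.77), Lncenc1 (-2.14) and Fndc3c1 (-2.03) in RNA.

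Cholesterol genes rose for 11 of 15 in RPF and 12 of 16 in RNA with 0 falls (14 and 14 adjusted over the list alone; adjusted p = 8.89e-07 and 1.05e-06, or adjusted p = 0.133 and 0.0293 with an estimated correlation). Primed epiblast markers fell for 5 of 10 and 6 of 10 with 0 rises (6 and 7 adjusted over the list alone; adjusted p = 3.76e-06 and 1.05e-06, or adjusted p = 0.0661 and 0.0293 with an estimated correlation). Endoderm markers fell for 6 of 11 and 8 of 14 with 0 rises (7 and 8 adjusted over the list alone; adjusted p = 2.1e-05 and 0.000105, or adjusted p = 0.364 and 0.441 with an estimated correlation). Hypoxia genes rose for 6 of 13 and 7 of 16 with 0 falls in both counts, Slc2a1 by 0.88 and 0.87 (adjusted p = 0.000278 and 0.000417, or adjusted p = 0.24 and 0.277 with an estimated correlation). Let-7 targets fell for 7 of 19 and 8 of 21 with 0 rises (8 and 10 falls with 0 and 1 rises adjusted over the list alone; adjusted p = 0.00117 and 0.00158, or adjusted p = 0.114 and 0.195 with an estimated correlation). Imprinted genes had 7 falls and 1 rise among 14 and 8 and 2 among 18 (7 and 1, and 9 and 2, adjusted over the list alone; adjusted p = 0.0124 and 0.01, or adjusted p = 0.141 and 0.195 with an estimated correlation), Grb10 at -1.18 and -1.10. Stress response genes passed in RPF with 5 falls and 1 rise among 15 (6 and 1 adjusted over the list alone; adjusted p = 0.0231, or adjusted p = 0.364 with an estimated correlation), Trib3 at -0.79. Of lists that passed over all mESC experiments, 5 passed in neither: naive factors with 9 rises and 5 falls among 21 in RPF and 9 and 4 among 22 in RNA (10 and 5, and 11 and 5, adjusted over the list alone; adjusted p = 0.0765 and 0.172), p53 targets with 3 and 2 among 19 and 7 and 2 among 20 (4 and 3, and 7 and 2; 0.983 and 0.618), matrix genes with 3 and 3 among 16 and 3 and 2 among 16 (4 and 3, and 3 and 2; 0.978 and 0.78), the earlier targets with 5 and 1 among 8 in each and in both counts (0.263 and 0.0601), and mesoderm markers, with 0 rises and 1 fall among 3 in RNA in both counts (0.618) and too few measured in RPF. Germ cell genes passed in RNA with 5 rises and 1 fall among 13 (5 and 2 adjusted over the list alone; adjusted p = 0.0141, or adjusted p = 0.195 with an estimated correlation), Mael at 1.35.

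Translational efficiency, the ratio of RPF to RNA, was tested as an interaction of genotype and assay over the 16 libraries. The changes of 1.12 ± 0.32 for Mbnl1 and 0.23 ± 0.16 for Trim71 did not pass. Of 12851 genes 0 rose and 1 fell by edgeR's quasi-likelihood test, 750 had an unadjusted p under 0.05, and DESeq2 called 13. The gene that fell was Tktl2, a transketolase-like gene (-4.08 ± 0.66, adjusted p = 0.0232), with 3 RNA counts over WT and 55 over KO, and 506 and 230 RPF counts. Its reads may be shared with its paralogues, which the counting could split. Its adjusted p ranged from 1.5e-08 with no filter on low counts to 0.408 without KO RNA replicate 2 of batch 2, and was 0.351 in batch 1 alone. It did not pass either without WT RNA replicate 1 or 2 of batch 1 (0.135 and 0.152) or of batch 2 (0.0956 and 0.197), KO RNA replicate 1 or 2 of batch 1 (0.101 and 0.105), or WT or KO RPF replicate 1 of batch 2 (0.064 and 0.0527). On simulated counts of this design the test recovered 57% of 2-fold and 10% of 1.5-fold changes, so most changes of the smaller size were not detectable here. Of the 22 lists tested 0 passed (lowest adjusted p = 0.752).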

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

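The checks for outlying libraries and the test of the difference between the cell lines were set before the results were seen, and no test of an explanation was run for the libraries below. Of 48 checks, each of 1 measure in 1 group of libraries, 6 marked an outlying library. Chance would mark about 1 in 20 if the checks were independent and each group had a single normal spread. The groups pool experiments that differ in depth, and the checks are not independent, so no excess over that rate is claimed.

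The share of counts taken by the most abundant gene was far above the others in 3 libraries. It was 10.239% in the KO mESC library that is replicate 1 of batch 2, where the next of the 10 KO libraries had 1.299%. That library also has the fewest counts of the mESC RNA set, 4.77 in units of 1e+06. Without it 5502 genes were called in KO mESCs instead of 5129, and 6140 instead of 5881 in the difference between cell lines, alternatives added after the data were seen. The share was 2.76% in the WT mESC library that is replicate 1 of batch 2, against 1.361% in the next. In this library and in KO replicate 1 of batch 2 the same gene, ENSMUSG00000045999, was the most abundant. The share was 4.401% in the WT RPF library that is replicate 2 of batch 2, against 1.563% in the next.

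Mitochondrial genes took 2.558% of counts in the KO mESC library of the first LIF experiment, where the next KO library had 1.551%. Ccr4 was at 0.665 CPM in WT replicate 3 of the 12-library mESC experiment, against 0.344 CPM in the next WT library, and both lie far below the KO mean of 66.1 CPM. It was at 0.109 CPM, 1 count, in WT RPF replicate 1 of batch 1 and at 0 in the other WT RPF libraries.

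The effect of the knockout differed between Ne4C and mESCs for 5881 genes by the interaction test. Over 30 splits of the libraries within each line, the real one included, 1 gave as many, the real one, and the highest of the others gave 109. The splits were drawn without regard to experiment. A chance dealing of the labels among these libraries is argued against. Whether lines or cultures came to differ by chance was not tested. The lines differ in cell type, culture and editing, and these could not be separated.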

How the results depend on the processing

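The alternatives added after the data were seen are batch 1 alone, the WT libraries split, the crossed pairings, the fits without the weak library or without X-linked genes, and the shared calls of the lines by other tests. Numbers of called genes stayed within 1.5 times under DESeq2, upper-quartile scaling and no filter, except for NHL against KO (DESeq2 149, no filter 115, instead of 66) and translational efficiency (DESeq2 13, no filter 41, instead of 1). The cause was not tested. Scaling moved the median of all genes by at most 0.047 on the log2 scale, in Ne4C, whose split with upper-quartile scaling is given above. The direction with more genes turned by DESeq2 in KO mESCs (2856 rises and 2593 falls), NHL (2426 and 2382), RING (1976 and 2261), NHL against RING (2086 and 1579) and Ne4C (3976 and 4013), with upper-quartile scaling in NHL (2266 and 2123), RING against KO (1270 and 1081) and Ne4C, and with no filter in RPF (1136 and 1244). It turned without single libraries in NHL, NHL against KO and NHL against RING, and without single experiments in KO mESCs and Ne4C. In Ne4C it turned with a replicate block (3355 rises and 3565 falls) and by limma-voom (3626 and 3727) too. Against 1.5-fold it turned in KO mESCs (237 and 168), NHL (221 and 193), RING against KO (147 and 115) and Ne4C (537 and 777). So no majority is claimed for the comparisons in which the direction turned. Against 1.5-fold, a stricter hypothesis, glmTreat called 405 genes in KO mESCs, 377 in the matched KO, 414 in NHL, 478 in RING, 38 for NHL against KO, 262 for RING against KO, 272 for NHL against RING, 1314 in Ne4C, 1508 in Huh-7, 139 in RPF, 280 in RNA of the same batches, 0 for translational efficiency and 1455 between lines. It shared 25 rises and 22 falls between mESCs and Ne4C and 20 and 11 between mESCs and Huh-7. Without an experiment term, which leaves level differences in the spread, 476 genes were called in mESCs and 1659 in Ne4C. Mbnl1 then did not pass in mESCs (0.96, adjusted p = 0.417; 7.48e-38 to 0.417 over its alternatives) or Ne4C (1.42, adjusted p = 0.188; 5.99e-19 to 0.188), and some, though not all, other named genes lost their calls. In the matched KO, NHL, RING, NHL against KO, RING against KO and NHL against RING, the 12-library experiment alone gave 1294, 1816, 1259, 191, 1188 and 924 genes, and the second LIF experiment alone, with deeper libraries, 6545, 6681, 6153, 2584, 4228 and 5210. Batch 1 alone gave 693 genes in RPF, 2154 in RNA and 0 for translational efficiency, from fewer samples. In the 12-library experiment alone Itpr2 in NHL, Fam198b between NHL and KO, Bnip3, Egln3 and Foxa2 between NHL and RING, Cxcr4 and Epcam in RING and Dlk1 in the matched KO did not pass, nor did Trib3 in RPF in batch 1 alone. With no filter Fam198b between NHL and KO, Egln3 between NHL and RING and Plppr4 in mESCs did not pass, and by DESeq2 S100a4 between NHL and KO and Plppr4 in mESCs did not. In batch 1 alone the Trim71 change in translational efficiency was -0.05 instead of 0.23. Mbnl1 in RING, 0.02, was 0.07 without WT replicate 3 of the 12-library experiment, and -0.03, -0.06 and -0.01 without its WT replicate 1 or RING replicate 3 or WT replicate 2 of the second LIF experiment; none passed. DESeq2 gave no adjusted p for Tktl2.

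Leaving out 1 library gave 3036 to 3599 genes in the matched KO, 3643 to 4195 in NHL, 2935 to 3691 in RING, 41 to 78 for NHL against KO, 1812 to 2363 for RING against KO, 2388 to 3180 for NHL against RING, 5712 to 7414 in Huh-7, 1447 to 2212 in RPF and 2018 to 4453 in RNA of the same batches. For translational efficiency it gave 0 to 3: 3 without KO RNA replicate 1 of batch 2, 2 without KO RPF replicate 1 or WT RPF replicate 2 of batch 1, and 0 without any of the 9 libraries whose absence ended the Tktl2 call. Leaving out 1 experiment gave 3482 to 4866 genes in mESCs, 5861 to 7155 in Ne4C and 4090 to 6018 between lines, and 7 to 12 called lists in mESCs and 5 to 6 in Ne4C instead of 3. With an estimated correlation 0 lists were called in KO mESCs, NHL against KO, RING against KO, NHL against RING, Ne4C, Huh-7 and RPF, 1 in the matched KO, NHL, RING and between lines, and 2 in RNA of the RPF batches. Shared calls fell from 1491 rises and 1351 falls for KO and NHL to 854 and 642 with KO from other experiments and to 624 and 519, or 770 and 692, with WT libraries split. For KO and RING they fell from 956 and 895 to 670 and 446 with KO from other experiments, and to 288 and 313, or 290 and 305, with WT libraries split. Of 4877 pairs of a named gene and an alternative, 4726 kept direction and side of the threshold, 141 lost the call, 6 gained it and 4 changed sign.

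Replicate numbers were not taken to pair the samples, since in no comparison were all same-number correlations over 0.1; they ran from -0.37 to 0.48. Within the 12-library experiment WT and KO were an exception, at 0.29, 0.48 and 0.47 with every library best with its own number. WT and KO of batch 2 were another, at 0.36. Their replicates 1 had the same most abundant gene, which was not the most abundant in replicates 2. NHL, RING, Ne4C, Huh-7 and RPF each had a library that was not best with its own number. These exceptions are a hint from the data, as the labels name nothing that a number shares. With a replicate block 5108 genes were called in mESCs, 4095 in the matched KO, 4768 in NHL, 4076 in RING, 79, 2617 and 3388 in the tests between altered lines, 6920 in Ne4C, 6651 in Huh-7, 1636 in RPF, 2897 in RNA of the RPF batches, 0 for translational efficiency and 5424 between lines. The block gave Mbnl1 a call between lines (0.29, adjusted p = 0.0429; 0.00975 to 1 over its alternatives), and with it Krt18 in RPF, Gpld1 and Plppr4 in mESCs and Tktl2 did not pass. Pairings crossed in Ne4C experiment 3 and RPF batch 1 gave 7045 and 2100. Depth was not tested as the cause of the low recovery of simulated 1.5-fold changes in the RPF batches.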

Other observations

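The gene groups and patterns below, and the tests of their explanations, were chosen after the data were seen, while the splits of the samples were planned before. Ribosomal protein genes, which fell in no fixed list, were lower in KO mESCs of the 2 batches with ribosome profiling. Of 80 such genes with an average log2 CPM over 1, 77 had lower RNA, with a median log2 fold change of -0.31, and 23 fell and 1 rose (camera p = 2.28e-09, p = 0.0342 with an estimated correlation). In RPF 40 of 44 were lower with a median of -0.54, and 23 fell and 1 rose (p = 2.61e-12, p = 0.00744 with an estimated correlation). Their share of RPF counts was 2.11% and 1.91% in WT and 1.52% and 1.56% in KO of batch 1, and 2.21% and 1.97% in WT and 1.25% and 1.48% in KO of batch 2. Their shares of RNA counts were lower in KO within each batch too, by little in batch 1, at 2.23% and 1.98% in WT and 1.84% and 1.96% in KO of batch 1, and 1.88% and 2.03% in WT and 1.3% and 1.78% in KO of batch 2. The lowest RPF share, 1.25%, belongs to KO replicate 1 of batch 2, whose RNA library is the one with the fewest counts. In the 12-library and second LIF experiments the median of all such genes tested in KO was only -0.05, with 2 rises and 2 falls. Over all 5 mESC experiments, which include the 2 batches, the median of 84 genes was -0.15 (p = 0.000175, p = 0.325 with an estimated correlation), and in Ne4C it was 0.07 over 81 (p = 0.213, p = 0.789 with an estimated correlation). For translational efficiency it was -0.21, with quartiles of -0.51 and 0.21 (p = 0.00392, p = 0.157 with an estimated correlation). These genes have many processed pseudogenes, so their reads may be shared, and each median kept its sign under the 2 other scalings, at -0.54, -0.52 and -0.53 in RPF.

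In Ne4C, 13 genes went from over 5 CPM in WT to under 0.1 CPM in KO, and 0 went the other way. They lie on 7 chromosomes: Aqp3, Cyba, Dtx1, Fgf4, Gas6, Hapln4, Hemk1, Hexa, Mmp2, Rpp25, She, Snx19 and Tert. In KO mESCs 0 genes did so, in NHL and RING 2 predicted genes each, and in Huh-7 SFRP1, while KRT17 and SFRP4 appeared. Runs of 25 neighbouring genes with a median beyond 0.35 were found in Ne4C on chromosomes 1 (-0.43), 3 (0.35), 7 (-0.54) and 17 (-0.4). In NHL they lay on chromosomes 3 (0.39) and 10 (0.41) and in RING on chromosome 4 (-0.6) beside X. In translational efficiency they lay on chromosomes 7 (-0.43) and 17 (-0.5). The Ne4C runs on chromosome 1 lay between 4.69 and 60.3 Mb and those on chromosome 7 between 3.11 and 12.1 Mb. The difference between lines had runs on chromosomes 1 (-0.49), 7 (-0.63), 10 (0.36), 11 (-0.39), 14 (0.42) and 17 (-0.39). Their cause was not tested, and their genes were kept in the counts of called genes.

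Ccr4, next to Trim71, was high in all 23 KO and NHL mouse libraries and low in all 23 WT and RING libraries. Human CCR4 in Huh-7 had 2 counts over the WT libraries and 15 over the KO libraries, too few to weigh. A change of the whole neighbourhood is argued against by the 18 other tested genes within 1 Mb, whose median in KO was -0.04 with quartiles of -0.11 and 0.2 (the median replaced a limit on every gene after the values were seen); 1 of them, Osbpl10, moved by over 1 (1.30 in KO, 1.26 in NHL, 1.46 in RING and 0.10 in Ne4C KO), and in Ne4C KO Susd5 did (-3.38). Read-through at a fixed share of Trim71 RNA is argued against too, since Ccr4 was 7.23% of Trim71 in NHL and 0.0486% in RING, 149-fold apart. An edited Trim71 allele that puts Ccr4 under Trim71 transcription stays open, as Ccr4 in KO was 9.51% of WT Trim71 in mESCs and 9.58% in Ne4C. Loss of RNA binding by TRIM71, which KO and NHL share and RING need not, is a candidate explanation that was not tested.

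Genes of the distal X chromosome stood higher in RING libraries. A shift of all X-linked genes is argued against by the proximal median of -0.06, and loss of TRIM71 function by the distal median of -0.03 in KO. A gain shared by the distal X genes of the RING line, such as an added copy in the cells sampled, stays open: 66.1% of distal genes were higher, fewer than a gain of all would give, and in Ne4C KO 65.1% were higher with a median of only 0.09. The mutation itself and the line that carries it cannot be told apart, since the labels name no second RING clone. This concerns Pgk1, Tex11, Tex13b, Cnksr2, Pdzd11 and Tsc22d3 in the RING comparisons, while Mid1 at the end of X fell.

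Meg3, Rian and Mirg were nearly lost in NHL and RING libraries. Loss of TRIM71 function is argued against by KO, where the largest change of the 3 RNAs was 0.21 in size and none passed the test. The culture of 1 experiment is argued against, since the smallest fall over the 3 RNAs, both lines and both experiments was -5.17. A general shift of imprinted genes as the whole cause is argued against by medians of -0.18 in NHL and -0.29 in RING over the 17 others, but 6 of these fell and 0 rose in NHL, and 7 and 0 in RING, so a smaller shift beside it stays open. An epigenetic change of this locus in the cells from which the mutant lines were grown may remain, and no test here bears on it.

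Other splits of the libraries were tested for each comparison, and in each number the real split is included. They were drawn over all libraries of the groups compared, without regard to experiment. For KO in mESCs the real split gave 5129 genes, 1 of 40 splits gave as many and the highest other gave 5. In the same order, the matched KO gave 3733 (1 of 30, 79), NHL 4410 (1 of 30, 350) and RING 3759 (1 of 30, 34). RING against KO gave 2317 (1 of 30, 51) and NHL against RING 3029 (1 of 30, 86). Ne4C gave 7809 (1 of 40, 1), RPF 2003 (1 of 34, 1) and RNA of the same batches 3317 (1 of 34, 0). A chance dealing of the labels among these libraries is argued against in these comparisons. Splits that mix differing groups add the difference to the spread and call few genes. They cannot show whether lines or cultures came to differ by chance. For translational efficiency the real split gave 1 gene, 1 of 34 splits gave as many and the highest other gave 0; this 1 call was lost without any of 9 of the 16 libraries, so it is not taken as a change beyond chance. For NHL against KO 2 of 30 splits gave as many as the real 66, and the highest other gave 177. That split keeps the NHL and KO libraries of the second LIF experiment apart and mixes those of the 12-library experiment. Within these 2 experiments alone 2584 and 191 genes were called, so that split still holds the labelled difference of 1 experiment. The splits therefore cannot decide on chance for NHL against KO. For Huh-7 the 10 splits are too few for a share under 0.05, with 1 as large, the real value 6924 and the highest other 0.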
